A study of Homo sapiens with 6 samples.

How the data were processed

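RNA from U251 cells, a human glioma line, was measured on 6 Affymetrix arrays, 3 from cells carrying a PARK2 transgene and 3 from control cells carrying GFP. Per the labels' protocols, both stable lines were made by viral infection and puromycin selection, and total RNA was extracted with a column kit and labelled with biotin by the array maker's standard protocol. The labels call the arrays of a group biological replicates and do not say whether they came from separate cultures or separate infections, so the p-values measure the spread between these samples, which may be technical.

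The deposited values are linear intensities, 1 per probe set and array. GCOS and MAS5 are named in the submitters' processing notes, with no version, scaling target or role, and the scaling of the arrays stays unknown. Array medians ran from 16.2 to 19.3 intensity units and 2% trimmed means from 137 to 168, so the arrays had not been brought to a common trimmed mean over all probe sets. Detection calls were not used here.

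The table held 54675 probe sets, of which 62 were control probe sets. Genes were named through GEO's platform annotation: 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none in the table used. Gene numbers were looked up in the RefSeq gene table of GRCh38.p14, which updated 0 symbols and lacked the number of 54 probe sets. That table was otherwise used only for the order of genes along chromosomes, and no coordinates are given because its build is not that of the array. A planned check of the labels by the level of the transgene is not reported here, so the group labels were taken as given.

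Intensities were turned into log2(value + 16), where 16 is a pseudocount, without further normalization. Fold changes are on this scale and understate the change of dim genes. Control probe sets and those with no gene or several genes were left out, as were those whose mean log2 value over the 6 arrays was under the 40th percentile of all non-control probe sets. The filter kept 32768 probe sets, with a lowest mean intensity of 9.87. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 13720 genes to test.

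PARK2 arrays were compared with control arrays by limma (version 3.58.1 in R 4.3.3) with an intensity trend in the variance model and Benjamini-Hochberg adjustment at 0.05. The variance model had 60.8 prior degrees of freedom with the trend against 4 residual ones, and 10.5 without the trend, so the smallest adjusted p-values lean on the model. In the text, rose, fell, higher and lower are used of genes past this threshold, and adjusted p is from limma unless another test is named. Gene lists, 38 in number with 862 different genes, were fixed before the data were examined, and 789 of those genes had a probe set of their own. Lists with at least 5 tested members (36 of 38) were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Named genes were fixed by rule before the data were examined. They were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members with the largest change per list, and EGFR, CTNNB1, MYC, CCND1, CCNE1, AXIN2 and PINK1. Where no member of a list passed, the 2 with the smallest p were named. This gave 161 genes, and genes named outside the rule are said to be so. No named gene had probe sets past the threshold in opposite directions.

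No arrays were duplicates. Pearson correlations of log2 values were 0.982 to 0.990 within groups and 0.957 to 0.964 between them. The 3'/5' ratio of the actin control probe sets ran from 3.83 to 5.31 in control and 3.53 to 5.66 in PARK2 arrays, and that of GAPDH from 1.04 to 1.17 and 1.02 to 1.06. Same-numbered arrays deviated together from their group means (r across genes of 0.379, 0.159 and 0.121 for replicates 1, 2 and 3), while pairs with other numbers ran from -0.270 to 0.161. This is a weak sign of pairing that comes from the data and not from the labels. The comparison was also fitted with the replicate number as a block.

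The limma and camera steps were tested on simulated arrays of 13720 genes for the comparison of PARK2 with control cells, with 200 genes changed. Of these, 47.8% were recovered at a change of 1.5-fold, 89.6% at 2-fold and 100% at 4-fold, and 14 unchanged genes passed. A planted list was found and 0 other lists were. The simulated noise was drawn separately for each gene, so it cannot show whether camera's preset correlation avoids false lists among genes that vary together. In the data the estimated correlation was 0.596 in the NRF2 list, 0.622 in the G2/M list and 0.165 in the neuronal list. The number of arrays limits the precision of every value.

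Alternatives fixed before the data were examined covered the filter, the pseudocount, normalization between arrays, the variance model, array weights, the choice of probe set, thresholds, the set test, the replicate block and the leaving out of each array. The weights are those of limma's gene-by-gene algorithm, taken because the default one did not converge. Scaling by the 2% trimmed mean and a neighbour correction were added after seeing the data. The neighbour correction subtracted from each fold change the median of the 100 tested genes around that gene on its chromosome, the gene itself left out. Its first version had included the gene itself. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.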

Results

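Gene expression was measured in U251 glioma cells that stably overexpressed PARK2 (3 arrays) and in control cells that overexpressed GFP (3 arrays), and the design holds this single comparison. It asks which transcripts differ between the PARK2 and the control line. Array medians were 18.40, 17.03 and 16.66 intensity units in control replicates 1 to 3, and 16.23, 17.63 and 19.25 in PARK2 replicates 1 to 3.

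The largest differences between PARK2 and control cells were changes of over 8-fold in single genes. BCHE, which codes for butyrylcholinesterase, rose from 4.68 ± 2.63 intensity units (SD, n = 3) in control cells to 661 ± 25.6 in PARK2 cells, a log2 fold change of 5.04 (SE 0.18). The control level lies under the filter floor of 9.87, so the size of this fold depends on the pseudocount (7.0 with 1 and 3.40 with 64 in place of 16). NEFL, the neurofilament light chain, rose from 91.3 ± 22.7 to 2982 ± 84.1, a log2 fold change of 4.83 (SE 0.15). MYH10, a non-muscle myosin heavy chain, fell from 1578 ± 266 to 69.0 ± 3.24, a log2 fold change of -4.22 (SE 0.16). LGR5, a receptor for R-spondins in Wnt signalling, fell from 808 ± 66.7 to 44.2 ± 3.71, a log2 fold change of -3.77 (SE 0.16). Limma's adjusted p was 3.4e-35 for BCHE, 1.1e-36 for NEFL, 1.5e-33 for MYH10 and 2.8e-30 for LGR5, and in each case all 3 PARK2 arrays lay on the same side of all 3 control arrays.

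The other 10 of the 12 largest rises had log2 fold changes from 4.02 to 4.76. They were the serine protease gene PRSS12 (4.76), the cancer-testis genes MAGEA12 (4.75) and MAGEA6 (4.15), the protocadherin PCDH10 (4.56), BEX1 (4.54), FAM133A (4.30), the complement regulator CD55 (4.26), the collagen cross-linking enzyme LOX (4.15), the secreted protease ADAMTS1 (4.03) and amphiphysin, AMPH (4.02). MAGEA6 and MAGEA12 have near-identical relatives, and their probe sets may not tell the family members apart. The other 10 of the 12 largest falls ran from -3.56 to -2.90 on the log2 scale. They were the growth-cone protein gene GAP43 (-3.56), CD180 (-3.51), the protease inhibitor SERPINA3 (-3.49), the sulfotransferase CHST1 (-3.48), the matrix Gla protein MGP (-3.43), TM4SF18 (-3.10), the transcription factor POU3F3 (-3.08), the unconventional myosin MYO5B (-3.03), LOXL4 (-2.95) and GIMAP2 (-2.90). These values are from the brightest probe set of each gene, and as the mean of the probe sets the changes were smaller by over 1.5-fold for PCDH10 (2.69), LOX (3.49), ADAMTS1 (3.20), MYH10 (-3.57), LGR5 (-2.66), GAP43 (-1.77), CHST1 (-1.97), MGP (-2.17) and POU3F3 (-1.65).

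**Figure D1:**
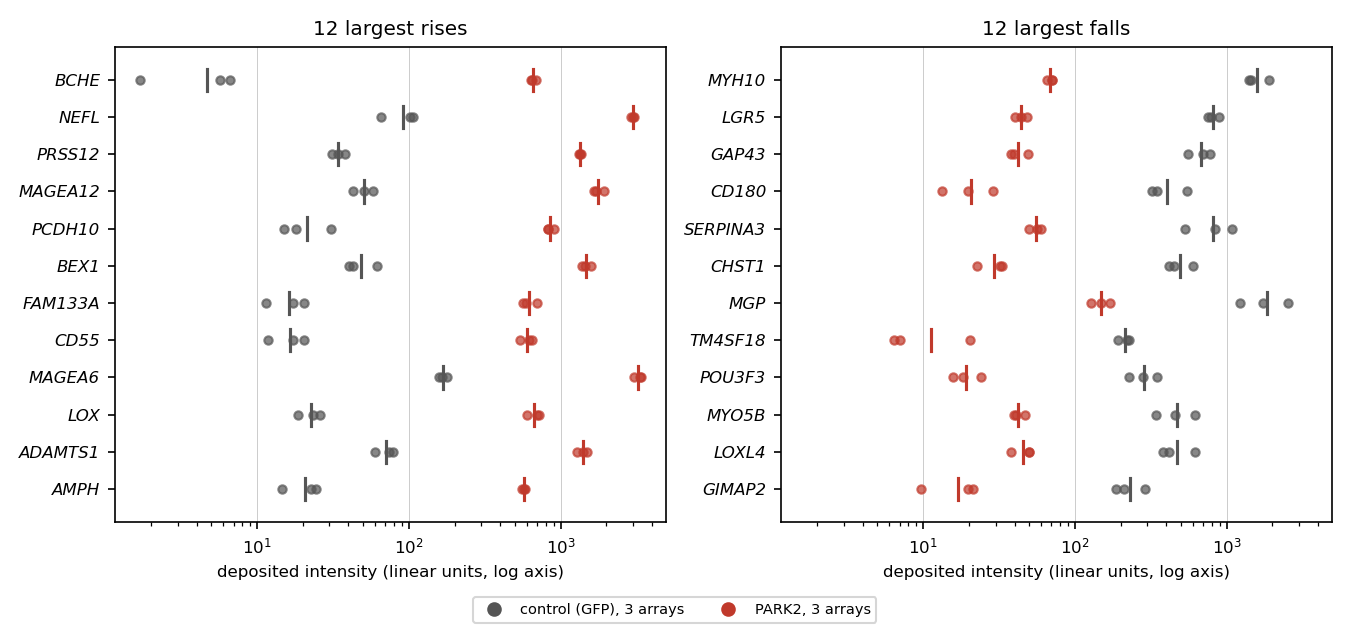
Deposited intensity (linear units on a log axis) of the 12 genes with the largest rise and the 12 with the largest fall, 1 point per array and a short vertical line at each group's mean (3 arrays per group). The groups do not overlap for any of these genes, with BCHE at a mean of 4.68 in control and 661 in PARK2 cells and MYH10 at 1578 and 69.0.

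Of 13720 genes tested, 1818 were higher and 2139 lower in PARK2 cells, together 28.8%. A change of 2-fold or more was seen in 431 higher and 336 lower genes, of 4-fold or more in 104 and 40, and of 8-fold or more in 37 and 10. The groups did not overlap for 5416 genes, where chance (10%) gives 1372. The higher count rested in part on control replicate 1, since 2799 genes were higher without it. With array weights 3075 genes were higher, and after a correction for neighbouring genes that was added after seeing the data 1371 were lower. The values as deposited gave more lower than higher genes, as did median centring (2324 higher and 2462 lower). Quantile normalization (2648 higher and 2550 lower) and trimmed mean scaling (2634 and 2511) gave more higher than lower genes.

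Genes of the NRF2 antioxidant response were higher as a group at camera's preset correlation. Camera gave the list an adjusted p of 1.1e-08. With an estimated correlation camera's unadjusted p was 0.127, and its adjusted p was 0.984, a value shared by all 36 lists tested. Another list test, fry's test of a common direction, gave an adjusted p of 0.083. Of 21 tested members 15 rose and 0 fell (16 and 0 adjusted over the list alone), and the median log2 fold change was 0.53. AKR1B10, an aldo-keto reductase, rose from 161 ± 31.6 to 1067 ± 86.8 (log2 fold change 2.62, SE 0.16, limma's adjusted p 9.0e-23), and ABCC2, an export pump for glutathione conjugates, from 13.5 ± 3.83 to 87.2 ± 17.5 (1.80, SE 0.21, adjusted p 5.9e-11, and 2.62 and 0.96 with pseudocounts of 1 and 64). AKR1C2 rose by a log2 fold change of 1.69, though its probe set may also read other AKR1C genes. Of members outside the rule for named genes and chosen after their values were seen, NQO1 (0.48), TXNRD1 (0.73) and GCLC (0.61) rose, and HMOX1 was at -0.27 (adjusted p 0.240). In 5 of the 9 other splits of the 6 arrays into groups of 3 the list passed as well.

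Genes of the G2 and M phases were also higher as a group at that setting. Camera gave the list an adjusted p of 0.00251, and 0.0577 without control replicate 2 and 0.0572 without PARK2 replicate 2. With an estimated correlation camera's unadjusted p was 0.389 (adjusted p 0.984, as for all lists tested). Fry's test of a common direction gave an adjusted p of 0.251. Of 30 G2/M genes 16 rose and 2 fell (17 and 4 adjusted over the list alone), with a median log2 fold change of 0.38. The mitotic kinesin KIF20A rose from 829 ± 81.05 to 1625 ± 164 (log2 fold change 0.96, SE 0.14, limma's adjusted p 6.4e-08), and ANLN, DLGAP5 and CENPE rose by 0.76, 0.72 and 0.66. AURKB (-0.42) and KIF23 (-0.41), named after their values were seen, fell. The G2/M list also passed in 3 of the 9 other splits of the arrays. Of 29 genes of G1/S and DNA replication 1 rose and 5 fell, the same counts adjusted over the list alone, among them the helicase subunit MCM4 at -0.78, and under quantile normalization 3 rose and 10 fell. Of 15 cyclins and CDK inhibitors 5 rose and 1 fell, also when adjusted over the list alone. The inhibitors CDKN1A (2.01, from 111 ± 19.6 to 491 ± 13.8), CDKN1B (0.71) and CDKN2D (0.76) were among the 5. CCND1 (-0.23, adjusted p 0.225) did not pass except with array weights (-0.34, adjusted p 0.0060), and CCNE1 was at -0.10 (adjusted p 0.712). Of 21 p53 target genes 5 rose and 4 fell (7 and 4 adjusted over the list alone), with ZMAT3 at 1.67 and GDF15 at 1.43 (0.67 as the mean of its probe sets). Of these 21, 8 rose and 4 fell under quantile normalization, and 5 rose and 1 fell after the neighbour correction.

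**Figure D2:**
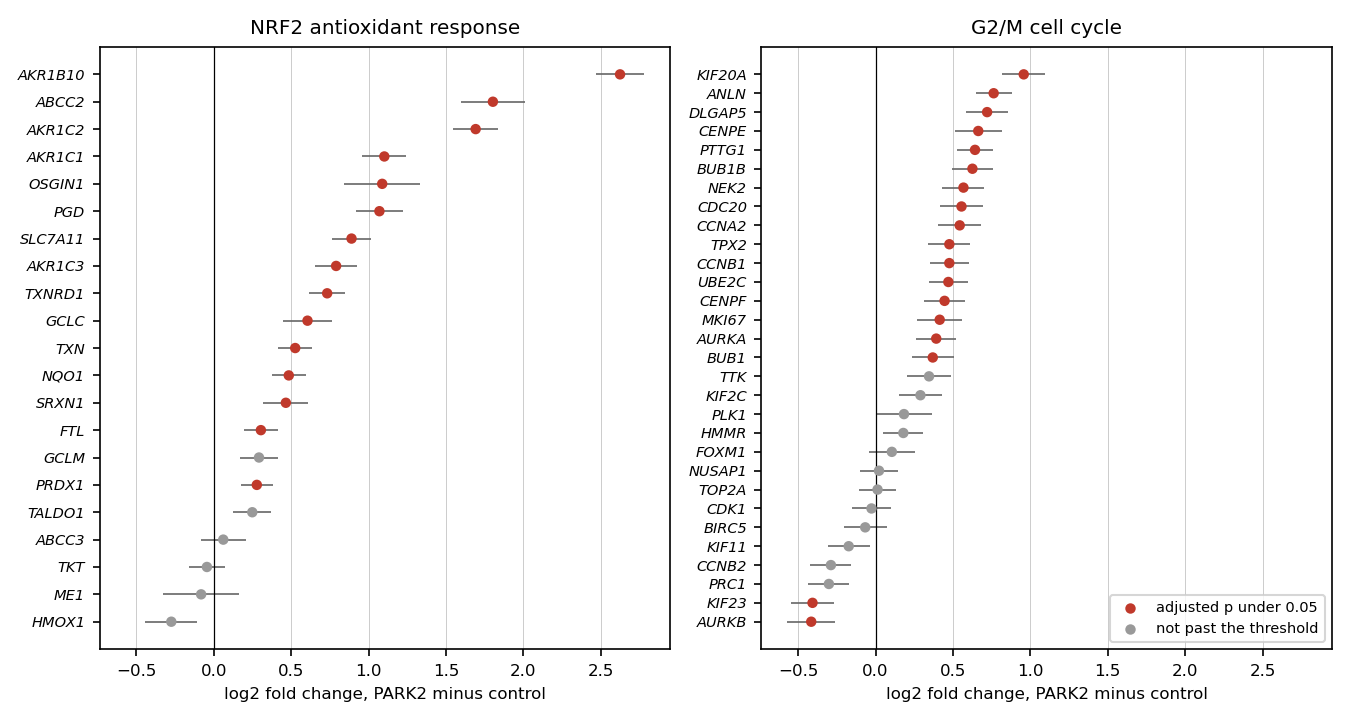
Log2 fold change, PARK2 minus control, of each tested member of the NRF2 antioxidant list (21 genes) and the G2/M list (30 genes), with bars of 1 standard error and colour for an adjusted p under 0.05. In the NRF2 list 15 members lie above 0 past the threshold and 0 below it, and in the G2/M list 16 lie above and 2 below.

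EGFR gave different values by probe set. Its brightest probe set was at 1211 ± 97.2 in control and 1164 ± 87.8 in PARK2 cells, a log2 fold change of -0.06 (SE 0.14, limma's adjusted p 0.825). Of the 7 EGFR probe sets past the filter, 3 were lower and 0 higher when all probe sets were tested. Those at -1.23 and -1.22 are marked _x_at and were dim, at 61.5 and 54.7 in control cells. The one at -0.58 was at 413 in control cells, and one at 746 did not pass (-0.15, adjusted p 0.637). The mean of the probe sets, which gives dim and bright ones the same weight, was at -0.53 (adjusted p 0.0069). Of 27 EGFR-MAPK output genes 11 rose and 8 fell, the same counts adjusted over the list alone. TRIB1 fell from 970 ± 161 to 177 ± 17.9 (log2 fold change -2.34), while the transcription factor ETV1 (1.91) and IL11 (1.29) rose. After the neighbour correction 10 of the 27 were higher and 4 lower. Of 25 receptor tyrosine kinases and ligands 6 rose and 5 fell, also when adjusted over the list alone. The ligand gene BTC (1.77) and FGFR3 (1.16) rose, and NRG1 (-1.68) and ERBB2 (-1.22) fell. The fall of NRG1 was seen in 1 of its 5 probe sets, and as the mean of the probe sets NRG1 was at -0.42 (adjusted p 0.0434), BTC at 1.12 and ETV1 at 0.86.

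Wnt genes moved both ways. Of 23 Wnt/beta-catenin target genes 6 rose and 6 fell (7 and 6 adjusted over the list alone, 9 and 6 under quantile normalization). AXIN2, a feedback inhibitor of the pathway, rose from 15.4 ± 9.41 to 58.0 ± 18.3 (log2 fold change 1.25, SE 0.23, limma's adjusted p 9.0e-06, and 1.99 and 0.61 with pseudocounts of 1 and 64) and FZD7 rose by 1.02, while LGR5 (-3.77) and MMP7 (-2.21) fell. Of 28 pathway components 9 rose and 7 fell (10 and 8 adjusted over the list alone), with WNT5B at 1.21, SFRP1 at 1.05 and TLE3 at -1.09. CTNNB1, which codes for beta-catenin, fell by 0.45 on the log2 scale (SE 0.13, adjusted p 0.0041), and MYC fell by 0.53 (SE 0.15, adjusted p 0.0042). The call of CTNNB1 was lost without PARK2 replicate 1 (adjusted p 0.0647), and that of MYC without control replicate 2 (0.0535) or PARK2 replicate 1 (0.0597). After the neighbour correction, CTNNB1 was at -0.16 (adjusted p 0.410) and MYC at -0.12 (adjusted p 0.653).

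Genes of mitophagy and autophagy showed no common direction. Of 31 such genes 7 rose and 4 fell, the same counts adjusted over the list alone. PINK1, a mitochondrial kinase, fell from 257 ± 34.3 to 137 ± 14.4 (log2 fold change -0.84, SE 0.17, limma's adjusted p 4.6e-05), and ATG12 rose by 0.72. The autophagy receptor gene SQSTM1 rose by 0.76 (SE 0.13, adjusted p 2.6e-06) on its brightest probe set, at 1545 in control cells. Another of its probe sets rose by 0.92 (adjusted p 0.0032 when all probe sets were tested). SQSTM1 was at -0.07 (adjusted p 0.845) on a dimmer probe set (91.7 in control cells), used when those marked _x_at and _s_at were dropped. As the mean of its probe sets, dim ones included, SQSTM1 was at 0.26 (adjusted p 0.267). Of 25 genes of the mitochondrial outer membrane and dynamics 6 rose and 4 fell (7 and 4 adjusted over the list alone). TFAM, the mitochondrial transcription factor, fell from 1277 ± 73.3 to 498 ± 27.4 (-1.33), TRAK1 fell (-0.78), and MFF rose (0.78). After the neighbour correction 4 of the 31 rose and 4 fell, and 4 of the 25 rose and 2 fell. Of 26 oxidative phosphorylation subunits 3 rose and 9 fell, also when adjusted over the list alone, with ATP5F1A at -0.72 and COX5A at -0.71, and 6 rose and 9 fell under quantile normalization. After the neighbour correction 0 of these 26 were past limma's threshold, and 3 had an unadjusted p under 0.05, while the median of the list was -0.13 against -0.07 before.

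Metabolic and stress genes were split. Of 23 genes of the glycolysis list 3 rose and 6 fell (3 and 7 adjusted over the list alone), with PFKFB4 at -1.21, HK2 at 1.07, PDHA1 at -0.98 and SLC2A3 at 0.59. As the mean of its probe sets HK2 was at 0.11 (adjusted p 0.653), where the others were dim, at 28.3 and 39.3 in control cells against 291 for the brightest. Of 16 hypoxia response genes 4 rose and 7 fell (5 and 7 adjusted over the list alone). LOX (4.15) and the peptide hormone gene ADM (1.60) rose, and DDIT4 (-1.47) and NDRG1 (-1.18) fell. Of 26 genes of endoplasmic reticulum stress and the ATF4 response 6 rose and 10 fell (7 and 10 adjusted over the list alone). The chaperone genes PDIA4 (-1.18) and SDF2L1 (-1.16) fell, and the cystine transporter SLC7A11 (0.89) and ASNS (0.84) rose. Of 17 cholesterol synthesis genes 1 rose and 3 fell, and of 18 genes of fatty acid synthesis and lipid handling 1 rose and 8 fell, both unchanged when adjusted over the list alone. STARD4 rose by 2.24, while SQLE (-1.18), INSIG1 (-1.03), SCD (-1.14) and FASN (-0.73) fell. After the neighbour correction 1 of the 18 fatty acid and lipid genes rose and 3 fell. Of 24 PI3K-AKT-FOXO genes 5 rose and 1 fell, also when adjusted over the list alone, with TXNIP at 1.49 and PIK3R3 at 1.15, but 12 rose and 1 fell under quantile normalization. Of 8 metallothionein list genes 4 rose and 0 fell, also when adjusted over the list alone, led by MT1G (0.60). The probe sets of MT1G, MT1H and MT1X are marked _x_at and may also read other metallothionein genes, which was not tested. As the mean of their probe sets MT1X was at 0.21 (adjusted p 0.243) and SLC30A1 at 0.0089 (adjusted p 0.977). MT1G kept its call under every left-out array, while MT1H, MT1X and SLC30A1 each lost theirs under at least 2, with adjusted p up to 0.291, 0.308 and 0.429. Camera gave the metallothionein list an adjusted p of 0.177 at the preset correlation. With an estimated correlation the list had an unadjusted p of 0.151 (adjusted p 0.984, as for all lists tested). After the neighbour correction its adjusted p was 0.0126 at the preset correlation, and no correlation was estimated there.

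Of 21 genes of ribosome biogenesis and MYC targets 1 rose and 6 fell (1 and 7 adjusted over the list alone), with RRS1 at -0.83 and WDR43 at -0.74. Of 20 cytosolic ribosomal protein genes 0 rose and 2 fell, of 24 proteasome and ubiquitin genes 2 rose and 6 fell, and of 17 heat shock genes 2 rose and 4 fell, each with the same counts adjusted over the list alone. Of the ribosomal protein genes 0 rose and 6 fell under quantile normalization, while 3 rose and 0 fell after the neighbour correction. That correction left 0 proteasome and ubiquitin genes higher and 1 lower, 0 and 3 heat shock genes, 0 and 4 ribosome biogenesis and MYC target genes, and 1 and 2 apoptosis regulators. RPL8 (-0.45) fell, but was at -0.0034 after the neighbour correction. Of 23 apoptosis regulators 2 rose and 4 fell, and of 12 housekeeping genes 1 rose and 2 fell, also when adjusted over the list alone, with BIRC2 at -0.54 and GUSB at -0.58. Under quantile normalization 7 apoptosis regulators rose and 4 fell.

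Matrix, signalling and inflammation genes moved both ways. Of 37 extracellular matrix and mesenchymal genes 12 rose and 10 fell (13 and 10 adjusted over the list alone), with MMP3 (1.39) and the cadherin CDH11 (1.29) higher and the collagen gene COL6A3 (-1.31) lower. Of 22 TGF-beta and SMAD targets 3 rose and 3 fell (5 and 4 adjusted over the list alone, 8 and 5 under quantile normalization), among them FSTL3 (1.60), INHBA (-2.02) and SMAD7 (-1.24). Of 23 YAP/TAZ targets 7 rose and 3 fell (8 and 4 adjusted over the list alone), with F3, the tissue factor gene, at 1.90 and ANKRD1 at -1.86. Of 22 interferon response genes 4 rose and 4 fell (5 and 5 adjusted over the list alone). IFI44L rose from 9.76 ± 5.05 to 237 ± 22.99 (3.31, and 4.56 and 2.03 with pseudocounts of 1 and 64), and HLA-B fell (-0.70). Of 20 NF-kB and cytokine genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), with VCAM1 at -1.39 and CCL2 at -0.80. Of 19 markers of the mesenchymal glioma subtype 1 rose and 8 fell (2 and 8 adjusted over the list alone, 5 and 8 under quantile normalization), including TIMP1 (-1.19) and TGFBI (-0.77). Of 17 proneural and stem cell markers 3 rose and 4 fell, also when adjusted over the list alone, with DLL1 higher and PTPRZ1 (-1.57) and HEY1 (-1.41) lower. DLL1 was at a mean of 3.24 in control cells, under the filter floor, and its value of 1.98 depends on the pseudocount (4.27 with 1 and 0.87 with 64).

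Neuronal markers were the single cell-type list that passed camera's test at the preset correlation. Camera's adjusted p was 5.3e-05. With an estimated correlation camera's unadjusted p was 0.033 (adjusted p 0.984, as for all lists tested). Without the filter on dim probe sets the list held 17 genes, of which 5 rose and 0 fell. Its median was then -0.02 and camera's adjusted p 0.0742. Of 9 tested members 6 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 0.48. NEFL (4.83), the synaptic genes SYT1 (2.50, from 13.7 ± 3.90 to 152 ± 12.5, and 3.41 and 1.47 with pseudocounts of 1 and 64) and SNAP25 (1.26), and the GABA-synthesis enzyme GAD1 (2.28) rose. Of 12 astrocyte markers 1 rose and 2 fell (2 and 4 under quantile normalization), of 7 oligodendrocyte lineage markers 0 rose and 2 fell, and of 9 endothelial and fibroblast markers 0 rose and 3 fell, each with the same counts adjusted over the list alone. S100B (-1.39), SLC1A3 (-0.72), PDGFRA (-0.67), FAP (-1.13) and THY1 (-0.80) fell. GFAP, the astrocyte filament gene, rose by 0.53 (adjusted p 0.0107) with overlapping groups, and its call was lost without control replicate 2 (0.124) or PARK2 replicate 2 (0.0857), while the mean of its probe sets was at -0.03. Lists of microglia and blood cell markers and of epithelial markers had 3 and 4 tested members and no list test. In the first 0 rose and 0 fell (CD3E at 0.27, adjusted p 0.478), and in the second 0 rose and 1, KRT18 (-1.12), fell, with the same counts adjusted over the list alone.

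**Figure D3:**
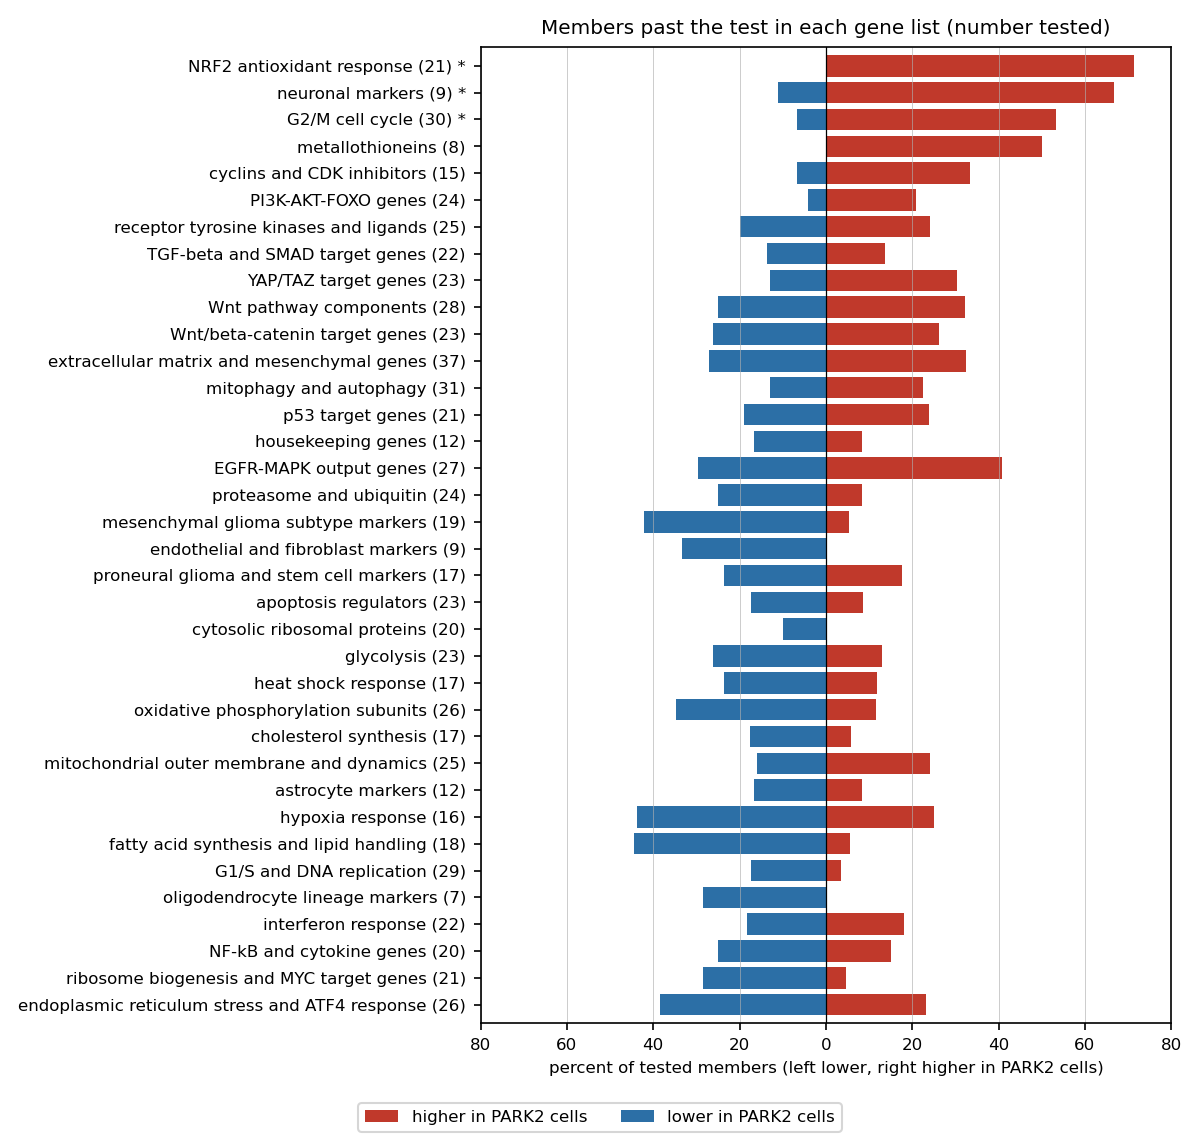
Percent of the tested members of each gene list that were higher (right) or lower (left) in PARK2 cells at an adjusted p under 0.05, for the 36 lists with at least 5 tested members, ordered by median log2 fold change. The number tested stands in brackets and an asterisk marks the 3 lists past camera's threshold at the preset correlation: NRF2 antioxidant response, neuronal markers and G2/M cell cycle.

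The other 33 lists did not pass camera's test (lowest adjusted p 0.177), and with an estimated correlation 0 of 36 lists passed and 1 had an unadjusted p under 0.05. Fry's test of a common direction and its test of change in either direction gave 1 and 35 lists past an adjusted 0.05. Neither fry test compares a list with the other genes. The test of change in either direction asks only whether members change, and 28.8% of all tested genes passed limma's threshold. The list past fry's test of a common direction was that of neuronal markers past the filter (fry's adjusted p 0.0042). It also had the unadjusted p under 0.05 with an estimated correlation (camera's p 0.033). The NRF2 (0.083) and G2/M (0.251) lists did not pass fry's test of a common direction. Median, mean and test differed in sign for the lists of Wnt/beta-catenin targets, EGFR-MAPK output, p53 targets, mitochondrial outer membrane, hypoxia, interferon and apoptosis genes, none of which passed.

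Genes that neighbour each other tended to shift the same way, a test chosen after seeing the data. Across 13675 genes in chromosome order, Spearman's rho of log2 fold changes was 0.288 between adjacent genes, 0.184 between genes 50 apart and 0.0970 between genes 200 apart, where genes are not independent replicates. In 100 shuffles of the gene order rho at 50 apart ran from -0.023 to 0.023. After the neighbour correction 1428 genes were higher and 1371 lower, and 2367 of these were among the genes named higher or lower before. The NRF2 list then had 14 members higher and 0 lower (median 0.43), the G2/M list 12 and 0 (median 0.29), and the neuronal list 5 and 1 (median 0.45).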

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

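The tests of neighbouring genes against gene dosage and against co-regulation, and the tests for neuronal cells, were chosen after the results they bear on were seen, and so was the neighbour correction itself. The test on rises replaced an earlier one on abundant markers, whose high level in control cells would hide a small share of neurons, and its bounds were changed again after its result was seen, as were those for gene dosage.

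Probe sets without a gene name in the table used were outside the comparison, and 410 of 4947 tested differed between the groups, 208 higher and 202 lower. The unnamed probe set with the largest rise went from 13.2 to 916 mean intensity units in PARK2 cells, a log2 fold change of 5.00 (limma's adjusted p 7.1e-13).

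Long runs of neighbouring genes shifted the same way. Co-regulation of adjacent genes alone is argued against by a rho at 50 genes apart that kept 0.637 of the value for adjacent genes, and a wave along the chromosomes that also splits arrays of 1 group by contrasts within groups, which reached at most 0.0839 of the real value at 50 apart. A wave that differs only between the groups was not tested. A difference in gene dosage between the lines over long runs may account for the pattern but stays open, since the rho of 0.184 at 50 apart restates the pattern and copy number was not measured here. Whether such a difference came with PARK2 or was there before the transgene was not tested, because the labels name no more than 1 stable line per group. An effect of PARK2 on wide chromosome regions also stays open as untested.

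The 144 genes changed by 4-fold or more are a separate pattern, since 85.4% of them kept a change of that size after the neighbour correction, which argues against long-run dosage as the whole cause. Neuronal cells in the PARK2 cultures may account for some of the rises: 9 of 13 neuronal markers dim in control cells did not rise, but many of these lie near background, so the test leaves this open. As a cause of the falls by dilution they are argued against, since 0 of 37 extracellular matrix and mesenchymal genes fell by 4-fold or more. Silencing, activation or loss of single genes in either line, and PARK2 itself, stay open and untested. The real grouping gave 144 such genes and the highest of the other splits 0, in 1 of the 10 splits of the 6 arrays, which are too few for a share under 0.05. Each other split mixes PARK2 and control arrays, so the group difference widens its spread and holds down its calls. The 0 therefore says nothing about chance.

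The NRF2 list kept a median log2 fold change of 0.43 after the neighbour correction and at least 0.53 under 3 other scalings, which argues against long-run dosage and against array scaling as the cause. A response to PARK2 and a difference between the lines that was there before both stay open, as the design has no other line. In the splits of the arrays 5 of the 9 other groupings also passed this list, at an adjusted p down to 2.6e-05, and those groupings still hold unequal numbers of PARK2 arrays.

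The real grouping gave 3957 genes past the threshold and the highest of the other splits 0, in 1 of 10 splits, with limma. Since every other split mixes the groups, their difference widens the spread within its arms, and few calls could be made there. The contrast is therefore no test of chance. At an unadjusted p under 0.05 the real grouping gave 5121 genes and the others 132 to 411. For gene lists, 3 of the 10 splits gave at least the real 3, and the highest of the others gave 4. Among the 3 other splits that part all 3 same-numbered pairs, as the real one does, 2 lists was the highest. With 10 splits no share under 0.05 can be reached.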

How the results depend on the processing

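Trimmed mean scaling and the neighbour correction were chosen after seeing the data. Counts of higher genes moved by over 1.5 times with array weights (3075 against 1818) and with a 1.5-fold minimum (1063), and ran from 1225 to 2799 when each array was left out, the highest without control replicate 1. Counts of lower genes moved as far when probe sets were counted in place of genes (3221 against 2139), after the neighbour correction (1371) and with the 1.5-fold minimum (1291), and ran from 1540 to 2629 when each array was left out. The 1.5-fold minimum is a stricter rule by construction, and for the others the cause was not tested. Of 3957 genes past the threshold, 2266 passed under every left-out array and all 3957 kept their sign. The share of higher genes among them was 45.9%, and went from 35.9% without control replicate 3 to 60.4% without control replicate 1. Shifted lists numbered 3, but 0 with an estimated correlation, 1 with fry's test of a common direction and 2 to 3 when each array was left out. They numbered 4 without the filter and 4 after the neighbour correction, which added metallothioneins (adjusted p 0.0126). Fry's test of change in either direction passed 35 lists, but it asks only whether members change and does not count shifted lists. The replicate block gave 1556 higher and 1897 lower genes and 3 lists. Among named genes it ended the calls of BCL2L1 (adjusted p 0.0793), TNFSF10 (0.0875) and SLC30A1 (0.0818) and changed no other call. Of 3167 values of named genes under other settings, 3024 kept direction and side of the threshold, 138 lost the threshold, 2 gained it and 3 reversed. The reversed ones were SQSTM1 (-0.073) and AKR1C1 (-0.0028) without probe sets marked _x_at and _s_at, and GFAP (-0.027) as the mean of its probe sets, and in each a dim probe set replaced or joined the bright one. All 33 named genes changed 4-fold or more kept direction and threshold under every setting in which they were tested, though 9 of the largest changes shrank by over 1.5-fold as the mean of the probe sets. Detection calls were not used, so for genes near the lowest mean intensity kept, 9.87, signal over background is unknown.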

Other observations

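The gene sets in this part, and the test on cancer-testis genes, were chosen after the largest rises were seen. Of 13 protocadherin genes of the beta cluster past the filter 9 were higher and 0 lower in PARK2 cells, and without the filter 5 of 17 were higher and 0 lower. The filter on the mean of all 6 arrays keeps silent genes that rose and drops those that did not, and no set test was made. PCDHB7 rose from 53.7 ± 4.88 to 208 ± 3.68 intensity units (SD, n = 3), a log2 fold change of 1.69 (limma's adjusted p 1.3e-12), and PCDHB14 from 135 ± 22.6 to 365 ± 27.5 (1.34, adjusted p 4.7e-10). PCDHB16 (0.83) also rose. These genes lie in a cluster of similar sequence, several of their probe sets are marked _x_at, and cross-reading between members was not tested.

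Cancer-testis genes, whose expression is normally limited to the germ line, were among the largest rises. Besides MAGEA12, MAGEA6 and FAM133A, SPANXB1 rose from 29.3 ± 1.78 to 153 ± 14.1 (log2 fold change 1.90) and MAGEA1 from 1.39 ± 0.61, under the filter floor of 9.87, to 45.5 ± 14.0 (1.80). IL13RA2, a receptor gene known from glioma, rose from 1701 ± 326 to 4115 ± 79.2 (1.28). A loss of silencing of the whole class could raise most of its members. Of 19 members past the filter 8 rose and 1, ROPN1 (-0.55), fell, with the same limit of the filter. Without the filter 7 of 63 members with a probe set rose and 0 fell, with a median log2 fold change of 0.089. Most members were thus not seen to rise. Most of the 63 did not pass the filter, and near background a rise could be missed, so the test leaves the hypothesis open. The bounds of this test were set again after its results were seen.

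The gene for NRF2 itself, NFE2L2, was at 1660 ± 199 in control and 2173 ± 359 in PARK2 cells, a log2 fold change of 0.38 (adjusted p 0.0257). KEAP1, its inhibitor, was at 0.18 (adjusted p 0.432) and CUL3 at 0.17 (adjusted p 0.353).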
